A study of Mus musculus with 4 samples.

How the data were processed

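Gene expression in single cells of mouse dorsal root ganglia from the neck downward was measured in 4 libraries made with the 10x Chromium v3 kit, which counts tags at the 3' end of transcripts. Of these, 2 libraries came from control littermates and 2 from Cdx2-Cre; Piezo2 flox/flox animals, in which Cre acts in the caudal embryo. Each library pooled 2 or 3 animals. Replicate 1 of both groups was taken at postnatal day 24 and replicate 2 at day 21, and the replicate number pairs 1 control with 1 mutant library.

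The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and barcode; the authors made them with Cell Ranger on genome build mm10, per the labels' processing notes. The version of Cell Ranger, the annotation release and the cell-calling settings are not given in the sources used here. The values were whole numbers with at least 500 UMIs per barcode. The 4 libraries share 28694 features, among them the transgenes Tdtomato and Cre, and 28339 of the gene identifiers matched GENCODE M21 on GRCm38, from which positions were taken.

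Depth per library ran from 77082782 to 87448400 UMIs. The barcodes numbered 13602 and 13355 for control and mutant replicate 1, and 21259 and 15154 for control and mutant replicate 2. These exceed the number of cells that the labels give as loaded per run.

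Cells with at least 500 genes detected and at most 10% of UMIs from mitochondrially encoded genes were kept. Doublets were called per library with Scrublet in scanpy 1.11.5 (expected rate 0.08) and removed. In 3 of the libraries Scrublet marked under 0.5% of the cells, and the cells above the 94th percentile of its score were removed there instead, which took out 654, 662 and 954 cells; in mutant replicate 2 its own calls took out 251. This left 10763 and 10790 cells for control and mutant replicate 1, and 15400 and 12024 cells for replicate 2. UMIs were scaled to 10000 per cell and log-transformed. Cells were grouped on 2000 variable genes (Piezo2, mitochondrial, ribosomal protein and sex-linked genes left out), 40 principal components and 15 neighbours, by Leiden clustering at resolution 1. Neurons were then clustered again with the same settings. A cluster was named "X-like" from markers fixed beforehand. A marker counted as detected when at least 10% of the cells had a UMI of it and its mean level exceeded that of the other clusters by a set factor. A single marker of other cells did not always exclude a cluster. Hbb-bt was among the top 10 genes of cluster 2, kept as proprioceptor-like, and Col1a1 among those of cluster 33, kept as Adelta-LTMR-like. Clusters of neurons judged to mix markers of neurons and of other cells were called mixed and left out of both. These took 41 of 3984 cells of neuron clusters in control replicate 1 and 55 of 6009 in mutant replicate 1, against 2600 of 6970 in control replicate 2 (37.3%, 95% Wilson interval 36.2 to 38.4, counting error only) and 94 of 4139 in mutant replicate 2. Neurons without a class name (497 in control replicate 1, 627 in mutant replicate 1, 768 in control replicate 2, 753 in mutant replicate 2) stayed in the sum of all neurons.

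Counts were summed per library over the cells of a population, since cells are not replicates. The populations were all neurons, A-fibre low-threshold mechanoreceptors (LTMRs; the Abeta-LTMR-like and Adelta-LTMR-like classes together), C-LTMRs, proprioceptors, the other neurons (peptidergic, Mrgprd-like, Mrgpra3-like, Sst-like and Trpm8-like classes together) and glia (satellite and myelinating Schwann cells together). Mutant and control sums were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr and a threshold of 0.05 on the Benjamini-Hochberg adjusted p. Every fold change is mutant over control with 2 libraries per group, and every SE is that of the edgeR coefficient on the log2 scale. The labels name no test, so the fit on group alone is the one reported first, and the fit with a replicate block stands beside it. Levels are CPM, the share of the summed UMIs scaled to 1e6 with the TMM factors applied, unless stated otherwise. For a gene without any count in 1 group, the fold is a limit computed at 3 counts over that group.

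The 30 gene lists and the cell type markers were fixed before the data were examined, and lists with at least 5 measured members were tested with camera in limma 3.58.1 (inter-gene correlation 0.01, log2 CPM with a prior count of 2), and also with an estimated correlation and with fry. The genes named were chosen by a rule also fixed before the data were examined: Piezo2; among genes past the threshold that moved the same way in both pairs, the 12 of smallest p in each direction for all neurons and A-fibre LTMRs and the 5 for the other populations; where fewer than 5 passed, the 5 of smallest p; up to 4 members of each list that passed and of the lists of immediate early genes, mechanosensitive channels and transcription factors; and the 3 of smallest p per class. Class shares were tested with edgeR on cell numbers and with an exact permutation test, whose smallest two-sided p with 2 against 2 libraries is 0.333. The difference between the genotype effects in mechanosensory neurons (A-fibre LTMRs, C-LTMRs and proprioceptors together) and in the other neurons was tested as an interaction with library as a block.

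The tests were run first on simulated counts with 200 genes changed at a log2 fold change of 2. Only genes above a set level were changed, so the calls do not describe scarcer genes. The simulated spread between libraries came from the blocked fit, which leaves out the replicate difference unless it is added. For all neurons, over 15178 genes, 207 were called, 200 of them changed. With a shared replicate effect (SD 0.4 on the log2 scale, 15153 genes), the fit on group alone called 178, all of them changed, and the blocked fit called 209, 200 of them changed. For A-fibre LTMRs the calls were 212 over 11205 genes, 200 of them changed, and with the replicate effect 192 and, blocked, 203 over 11167 genes. Among the lists, 1 was shifted and camera called it with an adjusted p of 4.48e-80, but with an estimated correlation the adjusted p was 0.0626, so that test has little power in this design. The simulated interaction over 15270 genes gave 204 calls, 200 of them changed. A 3-fold rise in the share of 1 of 10 classes was called with an adjusted p of 0.0146 by edgeR. The simulated classes were of equal size and varied less between libraries than several real ones. Real Adelta-LTMR-like cells, for example, were 3.78% ± 2.45 of control neurons (SD, n = 2). That call therefore does not show the power to find a loss, or a change in a scarce class.

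Alternatives set beforehand were the replicate block, RLE scaling in edgeR, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of at least 10 CPM in at least 2 libraries, at least 1000 genes per cell, up to 20% mitochondrial UMIs, doublets kept, equal cell numbers per class, other Leiden resolutions (0.5 and 2) for the shares, and each library left out in turn. Chosen after the data were seen were neurons with at least 5000 UMIs, the top 6% of doublet scores removed in every library, clusters with over 80% of cells from 1 library left out, neurons other than C-LTMRs, these with the replicate block, and a replicate term for the mechanosensory difference in the interaction. Neutrophil-like cells and clusters led by haemoglobin genes were not compared.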

Results

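Single-cell RNA was counted in dorsal root ganglia of 2 control and 2 Piezo2 mutant libraries, each a pool of 2 or 3 mice aged 21 or 24 days. Piezo2 is the mechanically gated channel of touch and muscle afferents, and the series asks how touch receptors develop without its activity. The libraries held between 77082782 and 87448400 UMIs. Neurons numbered 3943 and 4370 in control replicates 1 and 2, and 5954 and 4045 in the mutant replicates. Their median depth was 12541 and 9259 UMIs in the controls and 10053 and 15451 in the mutants. Control replicate 2 stood apart in depth: 38.1% of its neurons had under 5000 UMIs (95% Wilson interval 36.7 to 39.6), against 20.4% (19.2 to 21.7) in control replicate 1, 24.03% (22.97 to 25.14) in mutant replicate 1 and 20.8% (19.6 to 22.1) in mutant replicate 2.

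The targeted gene, Piezo2 (ENSMUSG00000041482, chromosome 18, 63010213 to 63387183, mm10), was lower in both mutant libraries. In all neurons it fell by 2.14 on the log2 scale (SE 0.233, edgeR adjusted p = 0.0261), from 212 ± 64.9 to 48.3 ± 6.04 CPM (SD, n = 2). It fell by 1.74 (SE 0.245, adjusted p = 0.0115) in A-fibre LTMRs, the myelinated touch neurons, and by 2.53 (SE 0.200, adjusted p = 0.00027) in C-LTMRs, the unmyelinated ones. In proprioceptors, the muscle afferents, the log2 change was -1.06 (SE 0.250, from 211 ± 30.6 to 101.5 ± 11.02 CPM, n = 2), which missed the threshold (edgeR adjusted p = 0.0741) and passed with the replicate block (adjusted p = 0.000309). Across the other neurons it was -2.48 (adjusted p = 0.0603, and 5.55e-05 with the block). Glia held 14.6 ± 4.16 CPM in controls and 6.81 ± 1.42 in mutants (n = 2, edgeR adjusted p = 0.5003, and 0.022 with the block). The deleted exons are not given in the labels, and the 3' tags that remain do not measure functional transcript.

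**Figure D1:**
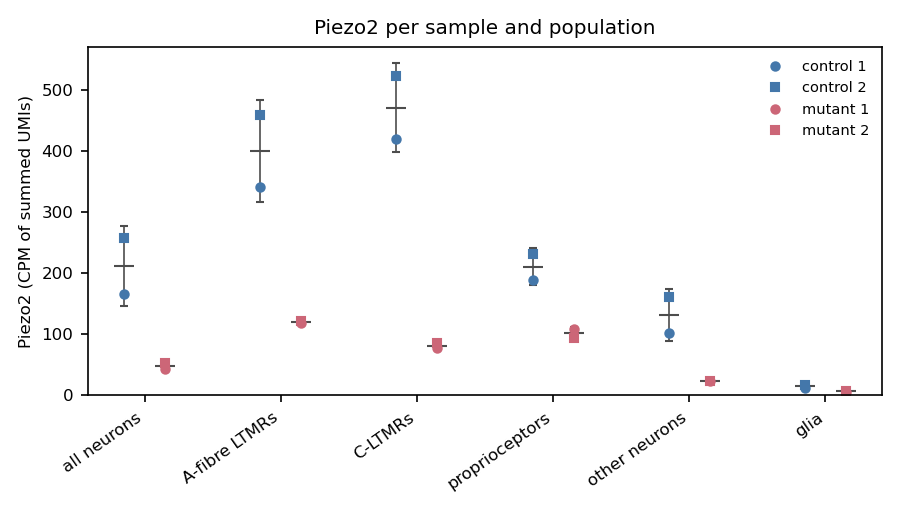
Piezo2 level in CPM of summed UMIs (vertical axis) per library in 6 populations (horizontal axis). Circles are replicate 1 and squares replicate 2, control in blue and mutant in red; bars give the mean and SD of 2 libraries, and both mutants lie below both controls in every population drawn.

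All neurons together answer which genes differ over the ganglion. Among the decreases, Th, the rate-limiting enzyme of catecholamine synthesis and a fixed C-LTMR marker, fell by 4.21 on the log2 scale (SE 0.229, adjusted p = 0.00336). Nxpe2 (chromosome 9, 48318006 to 48353454) fell by 5.62 (SE 0.222, adjusted p = 0.00119) from 17.5 ± 2.46 to 0.355 ± 0.0313 CPM (n = 2). Ceacam10, an adhesion molecule, fell by 5.26. The chemokine Ccl1 (-2.82), the cholecystokinin receptor Cckar (-2.36), the secreted C1q family protein C1ql4 (-5.86), the actin-severing protein Scin (-3.44) and the calcium pump inhibitor Pln (-4.72) also fell. Among the increases were Calb2 or calretinin (3.73), galectin Lgals3 (2.79), the neurokinin receptor Tacr3 (3.00), the growth factor Igf1 (2.35), the secreted protein Cthrc1 (2.44, although it fell by 2.27 in proprioceptors, adjusted p = 0.0183), the ephrin receptor Epha4 (1.91) and Syt17 (2.20). By edgeR 36 of 15359 genes passed, 8 higher and 28 lower, and all 36 passed with the replicate block, which called 1173.

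Of the fixed lists in all neurons, 8 of 30 shifted by camera and none with an estimated correlation, where the lowest adjusted p was 0.905. Axon guidance and adhesion genes were higher as a group (adjusted p = 0.000204; adjusted p = 0.905 with an estimated correlation): of 57, 1 rose over all genes, Epha4, and adjusted over the list alone 10 were higher and 2 lower. Ribosomal protein genes (adjusted p = 0.000756; 0.905 with an estimated correlation) and mitochondrially encoded genes (adjusted p = 0.00018; 0.905 estimated) were higher, with 0 members past the threshold in edgeR either over all genes or over the list alone. With the replicate block 4 ribosomal genes were higher and 1 lower, and 7 of 13 mitochondrial genes were higher. Immediate early genes were lower as a group (adjusted p = 0.0434; 0.905 estimated; 0.0509 with the block), with 0 of 21 past the threshold in edgeR either way and, blocked, 2 higher and 2 lower. Markers of other cells were lower too, each with an adjusted p of 0.905 under an estimated correlation: endothelial (adjusted p = 0.000412), macrophage (0.001), myelinating Schwann (0.024) and mural markers (0.0434, and 0.0509 with the block). The sensory transcription factors did not shift (adjusted p = 0.11) although Pou4f2, a POU-domain factor, fell by 1.52 (adjusted p = 0.0213), and the mechanosensitive channels other than Piezo2 did not shift either (adjusted p = 0.696). The count of changed genes rose when any 1 library was left out, to 297 without control replicate 1, 102 without control replicate 2, 81 without mutant replicate 1 and 78 without mutant replicate 2, with the lone library assumed to vary like the other group. DESeq2 called 221, the set without clusters dominated by 1 library 71, and neurons other than C-LTMRs 0 (375 with the block), both sets chosen after the data were seen. Both planned changes of the low-count filter lowered the count, to values given below with the other alternatives.

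In A-fibre LTMRs, the comparison closest to the study's subject, Rem2, a small GTPase that inhibits calcium channels, was almost lost: it fell by 5.83 on the log2 scale (SE 0.313, adjusted p = 0.000264; chromosome 14, 54476100 to 54480431), from 60.5 ± 3.86 to 1.02 ± 0.222 CPM (n = 2). Calb2 rose by 5.50 (SE 0.341, adjusted p = 0.000448), from 1.45 ± 0.523 to 63.1 ± 5.18 CPM (n = 2). The leak potassium channels Kcnk1 (-2.51) and Kcnk3 (-2.38) fell, as did Tmem72 (-3.44), the neuropeptide precursor Vgf (-2.58), Cckar (-3.64), the phospholipase Plcd4 (-3.13), the vesicle GTPase Rab15 (-2.02), Fam184b (-5.60) and Nxpe2 (-4.64). E530001K10Rik was not detected in either mutant and was at least 45.5-fold lower there. The cannabinoid receptor Cnr1 (2.00), the adhesion and guidance genes Mdga1 (2.10), Cntnap4 (2.01) and Sema5a (2.19), the lipid receptor S1pr3 (1.99), Lypd1 (1.90), the transcriptional inhibitor Id2 (1.90), Mgst1 (2.37), Calml4 (2.50), Gcnt4 (5.05) and the repair factor Aplf (3.21) rose. In total 205 of 11399 genes passed in edgeR, 84 higher and 121 lower, and all 205 passed with the replicate block, which called 1171.

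The lists in A-fibre LTMRs showed 7 of 26 shifts by camera, none of them kept with an estimated correlation. Axon injury and regeneration genes were higher (adjusted p = 0.00401; adjusted p = 0.929 with an estimated correlation): 2 of 15 rose over all genes, the transcription factors Jun (1.37) and Smad1 (1.24), and 6 adjusted over the list alone. Nuclear oxidative phosphorylation genes were lower (adjusted p = 5.89e-06; 0.98 estimated), with 2 of 77 falling over all genes and 2 over the list alone, the muscle-type cytochrome oxidase subunits Cox7a1 (-3.05) and Cox6a2 (-5.28). Immediate early genes were lower (adjusted p = 0.0484; 0.929 estimated), although the only 1 of 15 past the threshold over all genes was Jun, which rose, and adjusted over the list alone 5 were lower and 1 higher. Ribosomal protein genes were higher (adjusted p = 3.43e-06; 0.929 estimated) and cholesterol synthesis genes lower (adjusted p = 0.0484; 0.98 estimated), with 0 members past the threshold in edgeR over all genes or over the list alone and, blocked, 2 higher and 1 lower ribosomal and 2 lower cholesterol genes. For 3 of the cholesterol genes the decrease rests on control replicate 2, without which Fdps went from -2.06 to 0.27, Pmvk from -0.90 to 0.11 and Tm7sf2 from -0.86 to 0.10. Fibroblast markers were lower (adjusted p = 4e-06; 0.929 estimated), among them Col3a1 (-2.60), Dcn (-2.33) and Lum (-2.73), and haemoglobin genes were higher (adjusted p = 0.0447; 0.98 estimated), with 0 past the threshold over all genes and 1 over the list alone. Among them Hbb-bs went from 1.19 to -0.65 without mutant replicate 1 and to 3.31 without control replicate 2. The mechanosensitive channels did not shift (adjusted p = 0.473), with Kcnk2, a stretch-sensitive potassium channel, rising (1.38). The transcription factors did not either (adjusted p = 0.207), with Runx1 (-1.67) and Pou4f2 (-1.63) falling. A cluster led by the fibroblast marker Col1a1, number 33, belongs to the Adelta class, with 193 of its 194 cells from control replicate 2. It gave 193 of the 241 Adelta-LTMR-like cells of that library. The fall of Col3a1, Dcn and Lum is not given without it here. Cox7a1 is among its top 10 genes (-2.90 without such clusters). Without clusters of that kind, a choice made after the data were seen, 615 genes passed (2195 with the block). Leaving out control replicate 1 gave 2023 genes and leaving out control replicate 2 gave 480, and without the filter on low counts 912 passed.

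**Figure D2:**
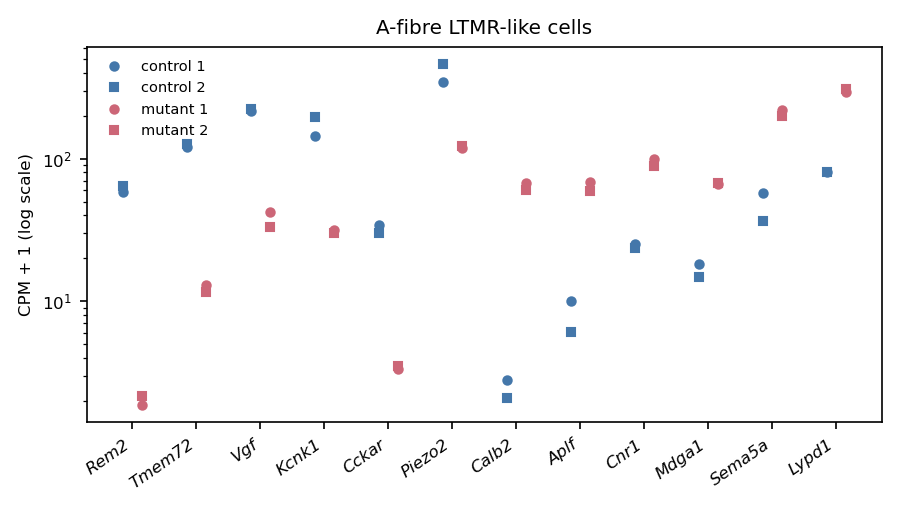
Level of 12 genes in A-fibre LTMR-like cells per library, as CPM plus 1 on a log axis. Circles are replicate 1 and squares replicate 2, control in blue and mutant in red; both mutants lie on the same side of both controls for every gene drawn.

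Over all 4 libraries, C-LTMRs had the most changed genes of the populations tested. With control replicate 1 left out, A-fibre LTMRs and proprioceptors had more. Th fell by 8.12 on the log2 scale (SE 0.335, adjusted p = 3.31e-05), from 428 ± 58.1 to 1.52 ± 0.701 CPM (n = 2), and the calcium-binding protein Necab2 (-6.44), Ly6h (-6.26), the tropomyosin Tpm2 (-5.48) and Ceacam10 (-5.30) fell with it. Lgals3 rose by 5.71 (SE 0.254, adjusted p = 3.38e-05), from 6.19 ± 0.234 to 325 ± 64.5 CPM (n = 2), and so did the homeobox factor Barx2 (7.42), the lipid kinase Dgkg (4.26), Smim5 (3.59) and the lysophosphatidic acid receptor Lpar3 (5.66), a fixed marker of Mrgprd neurons. In edgeR 1378 of 12194 genes passed, 638 higher and 740 lower. All 1378 passed with the replicate block, which called 2822.

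Which cells these are is not settled. Control C-LTMR-like cells formed clusters 11 and 15 and mutant ones clusters 34 and 35, so the values above compare different clusters. In clusters 34 and 35, 5 C-LTMR markers counted as detected (Fam19a4, Zfp521, Cdh9, Gfra2 and P2ry1), but none was among their top 10 genes. Across 73 class markers, genes not being independent replicates, the mutant cells correlated better with control Mrgprd-like cells of the other replicate (0.830 and 0.825) than with control C-LTMR-like cells (0.712 and 0.772). Across all genes the order differed between the mutants, with 0.983 for Mrgprd-like against 0.976 for C-LTMR-like in replicate 1 and 0.978 against 0.980 in replicate 2. Mrgprd, Ly86 and the C-LTMR markers Zfp521, Fam19a4 and Gfra2 were singled out after their values were seen. Mrgprd was at 1.49 and 0.663 CPM without TMM scaling in the mutant cells, against 160.7 to 272.7 CPM in Mrgprd-like cells of the 4 libraries. Zfp521 was at 75.1 and 90.4 CPM in the mutant cells, against 124.3 and 81.4 in control C-LTMR-like cells and 1.72 to 3.77 in Mrgprd-like cells. Ly86 went the other way, at 1295 and 923.8 CPM in the mutant cells, against 1.82 and 17.97 in control C-LTMR-like cells and 608.6 to 1799 in Mrgprd-like cells. Fam19a4 lay between, at 81.3 and 77.8 CPM in the mutant cells, against 345.8 and 333.4 in control C-LTMR-like cells and 24.8 to 37.3 in Mrgprd-like cells. Gfra2 does not tell these classes apart. It was at 222.9 and 232.9 CPM in the mutant cells, 308.9 and 266.8 in control C-LTMR-like cells and 336.5 to 381.8 in Mrgprd-like cells. Cluster 15 took 810 of its 812 cells from control replicate 2, with a median of 2070 UMIs.

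Among the fixed lists, C-LTMRs had 7 of 28 shifts by camera and none with an estimated correlation. Axon injury and regeneration genes were higher (adjusted p = 0.00805; adjusted p = 0.745 with an estimated correlation): of 16, 6 rose and 2 fell over all genes, and 9 and 3 adjusted over the list alone, with Jun (3.26), the adhesion protein Flrt3 (2.48) and the stress factor Atf3 (2.15) rising and the chaperone Hspb1 (-2.41) falling. GABA and glutamate receptors were lower (adjusted p = 0.0201; 0.745 estimated), with 7 of 20 falling and 3 rising, and 9 and 3 adjusted over the list alone: the NMDA receptor subunit Grin3a (-3.25) and the AMPA receptor subunit Gria3 (-2.91) fell and Grm7 (1.88) rose. Ribosomal protein (adjusted p = 0.00298), oxidative phosphorylation (0.0385) and mitochondrially encoded genes (0.00323) were higher, each at 0.745 with an estimated correlation. Of these, 2 of 73 ribosomal genes, Rpl36a (0.97) and Rpl29 (0.76), rose over all genes and 1 over the list alone, 8 of 13 mitochondrial genes were higher over the list alone, and 0 of 78 oxidative phosphorylation genes passed in edgeR either way. With the block 23 ribosomal genes were higher and 1 lower, 10 mitochondrial genes higher, and 13 oxidative phosphorylation genes higher and 1 lower. The mechanosensitive channels did not shift as a list (adjusted p = 0.357): 3 rose, including Trpa1 (2.75), and 2 fell, Asic1 (-2.92) and Tmem63b (-0.89), and over the list alone 4 and 2. Immediate early genes did not shift (adjusted p = 0.113), with 2 rising, Jun and Ier3 (0.97), and 3 falling, including Klf2 (-4.09) and Btg2 (-1.98), and 4 and 8 over the list alone. Of the transcription factors (adjusted p = 0.969), 5 rose, including Prdm8 (1.16), and 3 fell, including Pou4f2 (-2.67) and Tlx3 (-1.58), and 6 and 6 over the list alone. Markers of endothelial cells (adjusted p = 0.00298; 0.745 estimated), such as Cldn5 (-4.21), and of myelinating Schwann cells (adjusted p = 0.0417; 0.745 estimated), such as Mbp (-3.35), were lower. Dropping clusters with over 80% of cells from 1 library, chosen after the data were seen, gave 2115 genes (3662 with the block), no filter on low counts 2252, and control replicate 1, control replicate 2, mutant replicate 1 and mutant replicate 2 left out in turn gave 1799, 1640, 1118 and 1372.

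**Figure D3:**
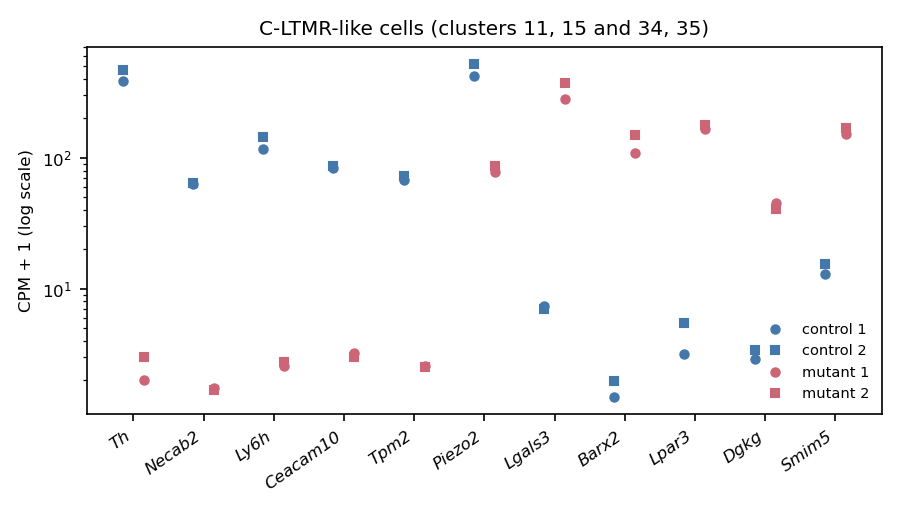
Level of 11 genes in C-LTMR-like cells per library, as CPM plus 1 on a log axis, with control cells from clusters 11 and 15 and mutant cells from clusters 34 and 35. Circles are replicate 1 and squares replicate 2, control in blue and mutant in red; both mutants lie on the same side of both controls for every gene drawn.

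In proprioceptors, Pln, which inhibits the calcium pump of the endoplasmic reticulum, fell by 5.71 on the log2 scale (SE 0.393, adjusted p = 0.00167), from 237 ± 86.5 to 4.53 ± 0.872 CPM (n = 2). The activin subunit Inhbb (-7.37), the polarity protein Inadl (-3.44), the matrix link protein Hapln1 (-4.01) and the channel adaptor Stac2 (-3.48) also fell. The iron reductase Steap3 (2.64), hexokinase Hk2 (5.45), Sema5a (2.86) and the adenylyl cyclase Adcy3 (2.49) rose, and Bmp3, not detected in controls, was at least 36-fold higher in mutants. In edgeR 210 of 10839 genes passed, 97 higher and 113 lower, and all 210 passed with the replicate block, which called 1152.

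By camera 4 of 25 lists shifted in proprioceptors, none with an estimated correlation and 6 with the replicate block. The block added oxidative phosphorylation genes (camera adjusted p = 0.0222) and neuropeptides (0.0321), both lower. Late activity-response genes were lower (adjusted p = 0.0224; adjusted p = 0.759 with an estimated correlation): 3 of 17 fell over all genes, Gadd45b (-3.17), Rgs2 (-2.01) and the synaptic pentraxin Nptx1 (-3.07), and adjusted over the list alone 9 were lower and 1 higher. Axon guidance genes were higher (adjusted p = 0.0224; 0.759 estimated), with 3 of 53 rising over all genes, Sema5a, Epha7 (1.87) and the protocadherin Pcdh8 (1.69), and 5 higher and 2 lower over the list alone. Ribosomal protein genes were higher as a group (adjusted p = 1.77e-16; 0.759 estimated), with 0 of 72 past the threshold in edgeR over all genes or the list alone and 36 higher and 1 lower with the block. Interferon response genes were higher (adjusted p = 0.0224; 0.759 estimated), with 0 of 10 past the threshold over all genes and 3 over the list alone. Kcnk2 rose (2.62) and Runx1 fell (-1.58). Cluster 2, with 151 of its 152 cells from control replicate 2, is part of this class and has Pln among its top 10 genes (-5.91 without such clusters). Without them, an alternative added after the data were seen, 934 genes passed (1742 with the block), and 1049 without the filter on low counts. The count was 2854 without control replicate 1, 445 without control replicate 2 and 133 without mutant replicate 2.

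The other neurons, those for heat, cold, itch and pain, showed few changes in the fit on group alone. These classes hold Piezo2 too. Its control mean was 208 CPM in Mrgprd-like and 182 CPM in A-fibre peptidergic-like cells, against 211 CPM in proprioceptors. In C-fibre peptidergic-like, Mrgpra3-like and Sst-like cells it was 68.8, 54.7 and 88.6 CPM. The antisense transcript 1500015A07Rik (chromosome 18, 61726390 to 61735917) fell by 2.54 on the log2 scale (SE 0.182, adjusted p = 0.0296), from 26.9 ± 3.73 to 4.63 ± 0.801 CPM (n = 2), and was the 1 of 14345 genes that passed in edgeR (280 at an unadjusted p under 0.05). Cthrc1, at 4.44 and 2.12 CPM in controls and 33.5 and 28.9 in mutants (log2 change 3.23, SE 0.302), missed the threshold (adjusted p = 0.0603) and passed with the block (adjusted p = 5.55e-05). Piezo2 (-2.48) had the same adjusted p as Cthrc1, followed by Spp1 (-2.30, adjusted p = 0.319) and Ighm (-1.03, adjusted p = 0.939). With the block 22 genes passed. More passed with no filter on low counts and, blocked, without clusters dominated by 1 library, as given below. Late activity-response genes (adjusted p = 0.00698), ribosomal protein genes (0.0129) and mitochondrially encoded genes (5.92e-05) were higher by camera, each with an adjusted p = 0.961 under an estimated correlation, and 0 members passed in edgeR over all genes or the list alone (0, 1 higher with 1 lower, and 0 with the block). The lists of immediate early genes, channels and transcription factors did not shift. DESeq2 called 8 genes and limma-voom 3, and the edgeR count was 3 without control replicate 1, 8 without control replicate 2, 16 without mutant replicate 1 and 148 without mutant replicate 2.

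Glia showed 4 genes past the threshold of 12794. Smr2 rose by 2.97 on the log2 scale (SE 0.256, adjusted p = 0.0134), from 2.27 ± 0.517 to 17.5 ± 3.22 CPM (n = 2). Clec2l (-1.61, adjusted p = 0.0177), the nuclear receptor Esrrg (-2.63, adjusted p = 0.0369) and the calcium buffer Pvalb (-1.63, adjusted p = 0.0369) fell, and Slc17a7, a vesicular glutamate transporter, was at -2.40 (adjusted p = 0.058). These genes are also found in neurons, where the control mean was 12.3 CPM for Smr2 against 2.27 in glia, 144 against 60.4 for Clec2l, 7.06 against 8.78 for Esrrg and 121 against 85.6 for Pvalb. Clec2l also fell in C-LTMRs (-4.85, adjusted p = 0.000217) and A-fibre LTMRs (-1.31, adjusted p = 0.0297), and Pvalb in Abeta-LTMR-like cells (-1.80, adjusted p = 0.000447). Pooled over all neurons the log2 changes were 0.82 for Smr2, -0.15 for Clec2l, -0.19 for Esrrg and 1.13 for Pvalb, which did not pass; Smr2 and Pvalb passed with the block (3.06e-08 and 3.3e-16). Proprioceptors, with the most Pvalb, had a log2 change of 0.60 (adjusted p = 0.316). Over 272 genes that neurons hold at more than 10 times the glial level, genes not being independent replicates, the changes in glia correlated with those in neurons at 0.450 and with those in endothelial-like cells at 0.417 (171 genes). Endothelial-like cells had log2 changes of 2.05, -2.03, -2.71 and -2.17 for the same 4 genes. In mural-like, fibroblast-like and macrophage-like cells Clec2l was at -1.16, -1.61 and -1.75 and Pvalb at -1.42, -1.61 and -1.62, without passing in edgeR. The share of free RNA from neurons in these cells was not measured, so the values are not read as changes of expression by glia. Presynaptic genes were lower by camera (adjusted p = 0.00105; adjusted p = 0.812 with an estimated correlation), with 0 of 36 past the threshold over all genes and 2 over the list alone. Ribosomal protein genes (adjusted p = 7.13e-08; 0.812 estimated) and mitochondrially encoded genes (0.0126; 0.884 estimated) were higher, with 0 members past the threshold over all genes in edgeR, and 1 and 0 over the list alone. Sex-linked genes were higher by camera (adjusted p = 0.0199; 0.812 estimated; 0.0517 with the block), which the sex of the pooled animals, not given in the sources used here, would move. With the block 73 genes passed, with DESeq2 14, with limma-voom 2, and with no filter on low counts 129. Without control replicate 1, control replicate 2, mutant replicate 1 and mutant replicate 2 the counts were 216, 114, 69 and 58.

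The comparison per neuron class asks where the changes lie; differences between single classes were not tested. In Abeta-LTMR-like cells Rem2 fell by 6.31 on the log2 scale (SE 0.354, adjusted p = 6.89e-10), and Calb2 (5.27) and Lypd1 (4.69) rose, among 475 changed genes of 10244 (235 higher, 240 lower; 1261 with the replicate block, 192 in DESeq2). In Adelta-LTMR-like cells the semaphorin co-receptor Nrp2 fell by 5.49 (SE 0.368, adjusted p = 0.000695), with Nxpe2 (-4.86) and Vgf (-3.32), among 284 of 9925 (122 higher, 162 lower; 927 with the block). Piezo2 and 1500015A07Rik were the 2 genes that fell in C-fibre peptidergic-like cells (-2.39 and -1.89; 74 genes with the block) and in A-fibre peptidergic-like cells (-2.58 and -3.81; 9 with the block). Both also fell in Mrgprd-like (-2.62 and -3.16; 14 genes with the block) and Mrgpra3-like cells (-2.64 and -3.65; 10 with the block), where Cthrc1 rose (4.70 and 6.48) as the only other gene. In Sst-like cells edgeR called 0 of 10858 (223 at an unadjusted p under 0.05, 57 with the block, 3 in DESeq2, 0 in limma-voom), and in Trpm8-like cells 0 of 8592 (438 at an unadjusted p under 0.05, 7 with the block, 0 in DESeq2 and limma-voom). The Abeta count was 732 without control replicate 1, 312 without control replicate 2 and 254 without mutant replicate 1. The Adelta count was 2437 and 595 without control replicates 1 and 2, and 183 and 180 without mutant replicates 1 and 2. Omitting control replicate 1, control replicate 2, mutant replicate 1 and mutant replicate 2 gave 72, 51, 7 and 54 genes in C-fibre peptidergic-like, 16, 10, 7 and 12 in A-fibre peptidergic-like, 8, 8, 31 and 170 in Mrgprd-like, 5, 3, 15 and 28 in Mrgpra3-like, 29, 7, 22 and 61 in Sst-like and 0, 2, 6 and 34 in Trpm8-like cells.

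**Figure D4:**
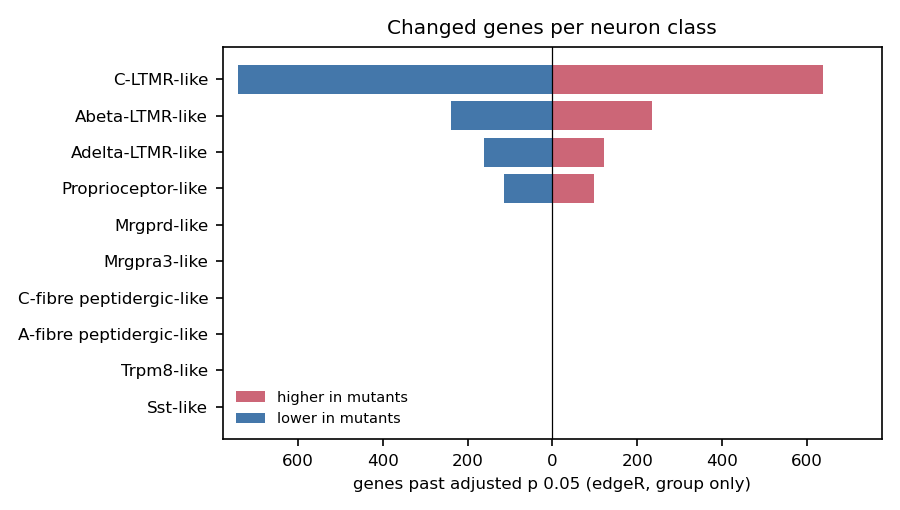
Genes past an adjusted p of 0.05 per neuron class (edgeR, group only), those higher in mutants to the right and those lower to the left. C-LTMR-like cells lead with 638 higher and 740 lower genes, and the 6 classes outside touch and proprioception have 3 or fewer each.

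Shares of the neuron classes were compared to see whether any class was lost. Each class name was given to cells of every library, but all but 1 of the control C-LTMR-like cells lie in clusters 11 and 15 and all mutant ones in clusters 34 and 35. The identity of the latter is not settled, so a loss of that class is not excluded. Abeta-LTMR-like cells made up 2.95% ± 0.095 of neurons in controls and 5.82% ± 0.298 in mutants (SD, n = 2; log2 ratio 0.98, SE 0.354), with an edgeR adjusted p of 0.259 (0.152 with the replicate block) and an exact permutation p of 0.333, two-sided. C-LTMR-like cells were 19.5% ± 9.20 and 16.3% ± 0.606 (n = 2), Mrgprd-like cells 19.1% ± 6.20 and 21.6% ± 4.25, Adelta-LTMR-like cells 3.78% ± 2.45 and 3.10% ± 0.329, and proprioceptor-like cells 3.97% ± 2.50 and 5.63% ± 1.27. The direction of 3 classes turned with the cells kept. C-LTMR-like cells were 15.2% in controls and 18.6% in mutants among neurons with at least 5000 UMIs, and 11.6% and 16.7% without clusters dominated by 1 library, where Adelta-LTMR-like cells were 1.77% and 3.19% and Mrgprd-like cells 21.4% and 19.5%. Of the 10 classes, 0 passed in edgeR and 0 with the block, and 1 had an unadjusted p under 0.05. Without control replicate 1, or without control replicate 2, 2 classes passed, and 5 passed without clusters dominated by 1 library, which was chosen after the data were seen and removes cells unevenly between libraries.

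Whether the mutation acts differently on mechanosensory neurons than on the others was tested as an interaction. Th (difference of log2 changes -7.16, SE 0.258, adjusted p = 8.79e-07), Tmem72 (-4.04), Necab2 (-3.57), the G-protein regulator Rgs5 (-3.50) and Fam122b (-3.23) had more negative effects in mechanosensory neurons. Ly86 (6.42), Barx2 (4.72, SE 0.163, adjusted p = 8.79e-07), Lpar3 (3.83), Dgkg (3.18) and Aplf (2.23) had more positive effects there. The classes differ: Ly86 was higher in C-LTMR-like (6.90) and Adelta-LTMR-like cells (2.44), and its log2 change was -0.70 in Abeta-LTMR-like cells and -1.41 in proprioceptors (adjusted p = 0.235 and 0.125; 0.0428 and 0.00656 with the replicate block). In C-LTMR-like cells such values compare different clusters. The effects differed for 1457 of 14746 genes, 852 in the positive and 605 in the negative direction. C-LTMR-like cells gave 8248557 of 11276872 and 9905848 of 16329770 UMIs of the mechanosensory sum in control replicates 1 and 2. In mutant replicates 1 and 2 they gave 11448991 of 18661916 and 12065885 of 22323430. An interaction without them is not given here, so the count is not read as common to the mechanosensory classes. The model takes library as its block, which does not remove a replicate effect on the difference between mechanosensory and other neurons. With a replicate term for that difference, added after the data were seen, 2091 genes passed. The count was 2289 without control replicate 1, 2186 without control replicate 2, 861 without mutant replicate 1 and 916 without mutant replicate 2.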

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

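The interaction was planned before the data were examined, as was the comparison of marker correlations, while the tests on control replicate 2, on the Mrgprd-like programme and on Mrgprd-like neurons counted as C-LTMRs were chosen after the result was seen.

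The genotype effect differed between mechanosensory and other neurons for 1457 genes by the interaction test in edgeR, with mutant and control differing in the same direction in both replicate pairs for each of the following 10 genes in mechanosensory neurons. Barx2 (difference of log2 changes 4.72), Ly86 (6.42), Lpar3 (3.83), Dgkg (3.18) and Aplf (2.23) had more positive effects in mechanosensory neurons. Th (-7.16), Rgs5 (-3.50), Tmem72 (-4.04), Fam122b (-3.23) and Necab2 (-3.57) had more negative ones.

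Th, Necab2, Barx2, Lpar3 and Dgkg also changed in C-LTMR-like cells, whose control and mutant members lie in different clusters (11 and 15, and 34 and 35). C-LTMR-like cells gave most UMIs of the mechanosensory sum in every library. Without control replicate 2, 1640 genes differed. That fit leaves 1 control library, and counts stayed high whichever library was omitted (1118 to 1799), so it cannot decide on the shallow and mixed cells of control replicate 2. As the whole cause of the separate clusters, these cells are argued against by control replicate 1. It had 508 C-LTMR-like cells in cluster 11 and 1 in cluster 34, while both mutants had 0 in cluster 11. Without clusters dominated by 1 library, chosen after the data were seen, 2115 genes differed. A wrong class name stays open, as the test written beforehand came out for it. In the correlation over class markers, the lead of control C-LTMR-like over the best other class was -0.118 in mutant replicate 1 (0.712 against 0.830). The gap was smaller in mutant replicate 2 (0.772 against 0.825). Mutant C-LTMRs may instead have shifted toward the Mrgprd-like programme. Of 31 Mrgprd-specific genes, 17 (54.84%) rose over 2-fold in mutant replicate 2, against 27.78% for the next class and 3.21% of genes specific to none. A wrong class name would raise these genes too, so this test cannot tell a shift from it. Plain Mrgprd-like neurons are argued against, although the clusters compared had already been split by expression and so were bound to differ in part. Of the genes over 4 times higher in C-LTMR-like than in Mrgprd-like cells of both controls, 61.02% stayed over 2 times higher in both mutants. This test was picked after the marker correlation was known, so the identity of clusters 34 and 35 remains unsettled.

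A reporter transcript, Tdtomato, was counted in these libraries and used in no comparison; its mean was 157.8 CPM in mutant neurons (SD 103.6, n = 2), above 33.9 CPM in control neurons (SD 25.6, n = 2), with an exact permutation p no smaller than 0.333 possible. Reporter UMIs were found in 15.8% and 37.9% of control neurons (replicates 1 and 2) and in 29.4% and 77.3% of mutant neurons, with the mutant higher in both replicate pairs. Whether the controls carry the reporter or a Cre allele is not given in the sources used here, which leaves the meaning of the difference open. It was also counted in glia, at 225 CPM in mutants (SD 22.5) and 70.1 CPM in controls (SD 46.4, n = 2).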

How the results depend on the processing

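The alternatives that keep neurons with at least 5000 UMIs, leave out C-LTMRs, remove the top 6% of doublet scores, add a replicate term to the interaction or leave out clusters with over 80% of cells from 1 library were chosen after seeing the data. For the 263 named genes, 4147 of 4759 values kept their direction and side of the threshold, 105 lost the call, 496 gained it and 11 reversed. Piezo2 in all neurons was lower under all 21 alternatives, from -2.42 to -1.78, with an adjusted p between 9.3e-33 and 0.182. It missed the threshold with no low-count filter (-2.13), with a mitochondrial share up to 20% (-2.11) and without C-LTMRs (-1.95). The cause of these and of the shifts below was not tested, except that the block removes the replicate difference and a low-count filter alters how many genes are tested.

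With the replicate block the counts of changed genes were 1173 in all neurons, 1171 in A-fibre LTMRs, 2822 in C-LTMRs, 1152 in proprioceptors, 22 in other neurons and 73 in glia. By class they were 9 in A-fibre peptidergic-like, 1261 in Abeta-LTMR-like, 927 in Adelta-LTMR-like, 74 in C-fibre peptidergic-like, 10 in Mrgpra3-like, 14 in Mrgprd-like, 57 in Sst-like and 7 in Trpm8-like cells. DESeq2 gave 221 in all neurons, 8 in other neurons and 14 in glia, and limma-voom 3 in other neurons and 2 in glia. With no low-count filter the counts were 9 in all neurons, 912 in A-fibre LTMRs, 2252 in C-LTMRs, 1049 in proprioceptors, 51 in other neurons and 129 in glia. At 10 CPM they were 16 in all neurons, 3 in other neurons and 2 in glia. Keeping Scrublet calls gave 3 in other neurons and 1 in glia, a mitochondrial share up to 20% gave 3 in other neurons, and so did removing the top 6% of doublet scores (3). Gene lists shifted by camera fell to 0 with an estimated correlation and 0 by fry, in all neurons and in A-fibre LTMRs alike.

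Neurons with at least 5000 UMIs and the block gave 578 in all neurons, 888 in A-fibre LTMRs, 2818 in C-LTMRs, 1105 in proprioceptors and 4 in other neurons, and that depth without the block gave 0 in C-fibre peptidergic-like cells by edgeR. Neurons other than C-LTMRs gave 0 by edgeR and 375 with the block. Without clusters with over 80% of cells from 1 library the counts were 71 in all neurons (903 with the block), 615 in A-fibre LTMRs (2195), 2115 in C-LTMRs (3662), 934 in proprioceptors (1742), 4 in other neurons (125) and 19 in glia with the block, and 5 neuron classes changed in share.

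Leaving out 1 replicate at a time, with the lone library assumed to vary like the other group, gave 78 to 297 genes in all neurons, 143 to 2023 in A-fibre LTMRs, 1118 to 1799 in C-LTMRs, 133 to 2854 in proprioceptors, 3 to 148 in other neurons and 58 to 216 in glia. Per class the ranges were 7 to 16 in A-fibre peptidergic-like, 254 to 732 in Abeta-LTMR-like, 180 to 2437 in Adelta-LTMR-like, 7 to 72 in C-fibre peptidergic-like, 3 to 28 in Mrgpra3-like, 8 to 170 in Mrgprd-like, 7 to 61 in Sst-like and 0 to 34 in Trpm8-like cells. Shifted lists ranged from 4 to 10 in all neurons and from 4 to 9 in A-fibre LTMRs, classes with a changed share from 0 to 2, and interaction genes from 861 to 2289.

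The log2 changes that reversed belong to genes that had not passed: without mutant replicate 1, Stom (-0.057) in all neurons, Hbb-bs (-0.653) in A-fibre LTMRs and Fosl2 (-0.115) in other neurons. Without control replicate 2 these were Fdps (0.268), Pmvk (0.111) and Tm7sf2 (0.099) in A-fibre LTMRs and Trpv2 (0.208) in glia. Without clusters dominated by 1 library Fdps was at 0.110 (0.105 with the block) and Trpv2 at 0.015, and with at least 1000 genes per cell Trpv2 was at 0.379. Over the 4 omissions of 1 library these genes ranged from -0.057 to 0.986 (Stom), -2.842 to 0.268 (Fdps), -0.653 to 3.315 (Hbb-bs), -1.465 to 0.111 (Pmvk), -1.345 to 0.099 (Tm7sf2), -0.115 to 1.487 (Fosl2) and -1.107 to 0.208 (Trpv2).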

Other observations

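The counts of shared calls, the choice of the glucocorticoid-responsive list and the test on heat-shock genes came after the result was seen, while the tests of that list in endothelial-like, mural-like and macrophage-like cells and those on sequence near Piezo2 and near Cdx2 were written before it.

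Some genes changed in all 4 mechanosensory classes, as named here after their values were seen. Rem2, the inhibitor of calcium channels, fell in Abeta-LTMR-like (-6.31), Adelta-LTMR-like (-5.14), C-LTMR-like (-6.17) and proprioceptor-like cells (-5.24). The leak potassium channel Kcnk1 (-1.62, -3.16, -2.31 and -1.87 in that order), Cckar (-3.93, -2.96, -2.66 and -3.01), the chaperone Clu or clusterin (-1.37, -1.96, -1.91 and -2.34), Kank4 and Necab3 fell as well, 6 genes in all. The 4 classes come from the same 4 libraries, so these calls do not count as independent. Control C-LTMR-like cells held Rem2 at 6.48 and 14.06 CPM, and control glia at 6.34 and 6.44 CPM. Its log2 change in glia was -3.49 (edgeR adjusted p = 0.152, and 0.0111 with the block). The share of free RNA in C-LTMR-like cells was not measured, so the fall of Rem2 there is not read as their own expression. Kcnk1 and Clu are also among the top 10 genes of cluster 2, and Kcnk1 of cluster 33, which come almost entirely from control replicate 2. Deptor, an inhibitor of mTOR (0.70 in Abeta-LTMR-like, 1.96 in Adelta-LTMR-like and 2.28 in C-LTMR-like cells), and Pik3r1, the regulatory subunit of PI3-kinase (1.47, 2.20 and 0.74), rose in these and in proprioceptor-like cells. In 3 or more classes 16 genes rose and 47 fell.

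Outside neurons, myelinating Schwann-like cells had 28 changed genes, 21 higher and 7 lower, with 91 by the block, 24 by limma-voom and 3 by DESeq2. The metallothionein Mt2 (1.69), Pcp4l1 (1.82) and the glucocorticoid-induced Tsc22d3 (1.33) had the smallest p. Macrophage-like cells had 4, the haemoglobin genes Hbb-bt (8.12), Hba-a2 (5.74), Hba-a1 (3.51) and Hbb-bs (4.56), all higher in mutants. These are erythrocyte transcripts, clusters led by them (18 and 22) are present in all 4 libraries, and the share of free RNA in macrophage-like cells was not measured, so the values are not read as expression by macrophages.

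Glucocorticoid-responsive genes were higher in mutant glia, with a mean log2 change of 0.507 in satellite glia-like cells (14 of 16 higher, camera adjusted p = 3.3e-09; adjusted p = 0.312 with an estimated correlation) and 0.855 in myelinating Schwann-like cells (adjusted p = 1.4e-09; 0.312 estimated), so neither call is kept with an estimated correlation. A higher glucocorticoid response of the mutant animals may explain this, since the list was also higher in endothelial-like cells, with a mean of 0.735 (camera adjusted p = 5.9e-10 in limma; 0.448 estimated), mural-like cells (0.479; 0.0005 and 0.339) and macrophage-like cells (0.576; 0.00014 and 0.339). Among neurons the mean was 0.378 in other neurons (14 of 15 higher, camera adjusted p = 1.3e-06 in limma; 0.312 estimated), 0.05 in C-LTMRs (0.888), 0.14 in A-fibre LTMRs (0.464) and -0.199 in proprioceptors (0.812). The list was chosen after the glial changes were seen and holds Tsc22d3 and Mt2, so its values in glia do not test it. All these cell types come from the same 4 libraries, so they do not count as independent. Stress of dissociation stays open, as the heat-shock list was at -0.019 in satellite glia-like cells over members that moved both ways. The immediate early genes were higher by camera in myelinating Schwann-like (mean 0.476, adjusted p = 0.0434 in limma) and endothelial-like cells (mean 0.412, adjusted p = 0.0172), but not with an estimated correlation (adjusted p = 0.753 in both).

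The transcript 1500015A07Rik fell in most neuron classes, and Rpl21 (-1.05) and Rpl29 (0.65) differed in all neurons with the block alone (adjusted p = 1.2e-14 and 2e-06, against 0.698 and 0.174 without it). 1500015A07Rik lies 1.274 Mb from Piezo2, so sequence carried along with the Piezo2 allele is a candidate explanation: 4.494% of 89 genes within 10 Mb had an unadjusted p under 0.05 in other neurons, against 1.921% elsewhere (Fisher's exact p = 0.0943). The named transcript is among them, and without it the share was 3.409%, which leaves the explanation open. Rpl21 lies 0.464 Mb from Cdx2, where the share was 1.875% of 160 genes against 1.938% elsewhere (Fisher's exact p = 1), and 1.258% without Rpl21. This is a low share that the few genes leave open. The share lay under the bound of 2.907% (1.5 times that elsewhere) set beforehand, as predicted without such linkage. The rule set beforehand named no interval, and the 95% exact interval of the share reaches 5.38%, above that bound. Where the Cdx2-Cre transgene lies is not given in the sources used here. Genes near Cdx2 need not be linked to the transgene, so this test cannot decide on sequence carried with it.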
